A study of Drosophila melanogaster and Mus musculus and Rattus norvegicus with 22 samples.

How the data were processed

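The series holds 22 samples in 19 groups, from the fruit fly Drosophila melanogaster, mouse, rat and rhesus monkey. RNA was sequenced from 6 h fly embryos injected with double-stranded RNA against GFP (the control, 2 libraries), DMAD (2 libraries) or Jumu (1 library, called set 1 here, and 2 further libraries, called set 2 here). Per the labels' protocols, mRNA of set 2 was purified with another kit than that of all other RNA libraries. DNA carrying N6-methyladenine (6mA) was enriched with an antibody (MeDIP) from fly head and larval fat body, from hippocampus and spleen of mice aged 3 months and rats aged 2 months, and from brain and spleen of rhesus monkeys aged 3 years. Per the labels, DNA of 0.75 h fly embryos was also pulled down with DMAD-CD, a form of the DMAD protein. Single 6mA positions came from single-molecule real-time (SMRT) sequencing of fly heads with DMAD knocked down. DMAD is the fly Tet gene product, which removes 6mA from DNA, and Jumu is a Fox family protein named in the series title as a reader of 6mA.

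Expression values were FPKM (fragments normalised to transcript length and library size) as deposited by the authors, per the file headers. Per the submitters' processing notes, the GFP, DMAD and set 1 data involved FastQC, STAR, TopHat2 and Cuffdiff, and the set 2 data FastQC, TopHat2 and Cuffdiff, on the fly build dm6. Versions, the strand setting of the counting and the pooling of replicates were not given in the sources used here. Each condition had 1 FPKM column. The GFP, DMAD and set 1 columns stood in separate tables with the same 17368 genes, and whether they were scaled together was not stated. The set 2 column stood in another table of 13445 genes. That table also held 1 column of values named wt, which matched no sample label and was not used. It may be the control of set 2, in which case the values of set 2 over GFP compare it with another control than its own. The set 2 column was assigned to the 2 numbered Jumu libraries because the other Jumu library has a table of its own. The name of the GFP column ends in 1, so it may hold the first GFP library alone, and every ratio to GFP rests on it. Because each condition had 1 column, nothing below has a replicate check, and no spread between libraries could be taken into account.

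Peak positions and the score of each peak were the authors' own, as deposited. The score was a whole number of at least 13 in every list, on a scale that was not stated, and was used only to rank peaks within a list. Per the submitters' processing notes, the peak data involved Bowtie2 and MACS2. The peak names in the deposited lists showed that each list was called on 1 library against 1 comparison library. Both mouse lists shared an input labelled as spermatocyte, both rat lists an input labelled as testis and both monkey lists an input labelled as heart, so an input never came from the tissue that was enriched. The comparison libraries themselves were not analysed here. Fly positions are on dm6 per the labels. The builds of the mouse, rat and monkey lists were not given in the sources used here, and their positions are printed as the authors gave them. SMRT sites were single positions with a strand, and their deposited score was 0 throughout, so no score or coverage could be used and the reading depth behind each site is unknown.

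The depth of the RNA libraries is unknown, because FPKM keeps no read number. Genes with low FPKM gave a relative depth from the most frequent ratio between columns. For values under 0.3 FPKM it was 0.966 of the GFP column for DMAD (755 genes, 28.1% of them within 0.1 log2 of that ratio) and 0.707 for Jumu set 1 (587 genes, 24.5%). For set 2 only 9.98% of 1022 genes lay that close, so its value of 1.60 is weak. An FPKM of exactly 0 can be a failed estimate. The 37 genes of the mitochondrial genome, which all cells transcribe, were listed at 0 in the GFP, DMAD and set 1 columns, and short RNAs such as snoRNAs often were, so such genes are only said to be listed at 0.

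Gene symbols came from a table of fly gene names, in which 17075 of the 17368 identifiers had a symbol. Gene positions came from a gene table of the Release 6 plus ISO1 MT assembly, which holds no strand, exons or introns. No genome sequence was used. Positions were therefore described as in a gene, within 1 kb of a gene or farther away. The planned shares in promoters, exons and introns, and the sequence context of the SMRT sites, were not analysed here. Genes without a symbol are not reported here by name.

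Changes in expression were computed as the log2 ratio of FPKM + 1 between columns, which understates the change of genes with low FPKM. Genes with a mean FPKM of at least 1 over the columns compared were used, and a gene was counted as higher or lower when its log2 ratio was at least 1 in size. This is a rule of size and no test. The moderated test planned for replicate columns could not be run. For the Jumu comparison, set 2 had been planned as the main data if its table also held the GFP control. No column there carried that label, so set 1 was compared with GFP, and set 2 was set against GFP across separately normalised tables as an alternative.

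A total of 24 gene lists had been fixed before the data were examined. A list with at least 5 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean FPKM. A list is called outside the random range when its percentile was under 2.5 or over 97.5. Percentiles describe these columns and are no p-values, since genes are not replicates. The genes named were chosen by a rule fixed at the same time. It took the knocked-down genes and zld, the 8 largest rises and 8 largest falls per comparison among genes with at least 5 FPKM in either column, and up to 4 members of each of the 6 lists with the most extreme medians. The largest rises and falls were mostly snoRNAs listed at 0 in one of the columns. Protein-coding genes above 0 in both columns were therefore taken by the same rule, a choice made after the values were seen. Some genes named from other tables were likewise chosen after their values were seen, which is said where they appear.

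Genes with a DMAD-CD site in the gene or within 1 kb of it were compared with all other genes by the difference in median log2 ratio. Genes without a symbol have no known position, but were kept among the genes without a site. Their lengths and bins in the matched settings were therefore not their own. The difference was set against 100000 random reassignments of the site label within deciles of mean FPKM. The planned permutation p and Fisher test over genes are replaced by the number of reassignments as far out, because genes are not replicates. Peak lists were compared by overlap of at least 1 bp, against 100 shuffles that moved the peaks within their chromosome. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Fixed lists among protein-coding genes with a peak were tested by permutation within deciles of gene length with 100000 resamples, two-sided, and adjusted by the Benjamini-Hochberg method over 66 tests. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 11.

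The rule of size, the list percentiles, the reassignment of genes and the overlap count were tested on simulated data. With 200 of the 8669 genes of the DMAD comparison changed, the rule of size recovered 98 (49%) at a log2 step of 1 and 199 (99.5%) at a step of 2, and called 5 and 6 unchanged genes. Of 100 random lists without a change 93 lay inside the random range, and of 100 lists shifted by -0.3 a total of 93 lay below it. For the DMAD-CD comparison 97 of 100 unchanged sets lay inside the reassignment range, and all 100 sets shifted by 0.15 lay above it. In all these checks the simulated log2 ratios had the same normal spread for every gene. That spread was narrower than in the data, where the robust SD (from the median absolute deviation) was 0.354 for DMAD, 0.440 for set 1 and 0.512 for set 2. The numbers recovered and wrongly called therefore do not carry over to the data. The overlap count found 1119 of 5000 simulated peaks, the same as a full search.

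Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, columns centred on their median, quantile normalization, a log2 ratio of 1.5 and set 2. For peaks they were matching on gene length, sites near gene ends, a reciprocal overlap of 50%, the peaks at or above the median score, a flank of 2 kb, and peaks without the mitochondrial genome. Alternatives added after seeing the data were protein-coding genes above 0 in all columns compared and peaks moved by at most 100 kb. They also included leaving out repeated gene arrays (histone, Stellate, X ribosomal DNA and 5S genes) with the mitochondrial genome, leaving out windows dense in SMRT sites, the gene body alone, and matching on or leaving out bins dense in DMAD-CD sites. The settings of the DMAD-CD comparison were also applied to set 2, and quantile normalization to the gene lists, after seeing the data.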

Results

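The expression data gave 4 columns of FPKM for 6 h fly embryos, 1 each for the GFP control, DMAD knockdown, and sets 1 and 2 of Jumu knockdown. In this order they listed 8801, 8386, 8286 and 8217 genes at 1 FPKM or more, and their FPKM summed to 1002126, 1131265, 966049 and 961161. The fly DNA data gave 5570 DMAD-CD sites of 0.75 h embryos, 5361 peaks of 6mA in head and 6591 in larval fat body, with median widths of 418, 362 and 329 bp, and 1938 single 6mA sites of DMAD knockdown heads. The mammalian data gave 35255 peaks of mouse hippocampus, 24707 of mouse spleen, 28281 of rat hippocampus, 63594 of rat spleen, 12579 of monkey brain and 28177 of monkey spleen. Each column and each list stands alone, with no replicate of its own, so no difference below was measured against a spread between libraries.

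The knocked-down genes were examined first. Tet, which encodes DMAD (FBgn0263392, 3L 2786207 to 2879158), stood at 79.7 FPKM in the control and 24.8 in the DMAD knockdown column, so 31.2% was left, and at 65.4 in Jumu set 1 and 49.2 in set 2. The forkhead gene jumu (FBgn0015396, 3R 10350182 to 10361612) stood at 90.6 FPKM in the control, 29.3 in set 1 (32.3% left), 42.5 in set 2 (46.9% left) and 78.6 in the DMAD column. Falls of this size were rare among genes expressed within 2-fold of the target, since 8 of 2791 such genes lay as low as Tet in the DMAD column and 6 of 2645 as low as jumu in set 1. The pioneer factor gene zld (FBgn0259789, X 19766465 to 19783548), which opens early embryonic enhancers, stood at 137 FPKM in the control, 102 in the DMAD column, 159 in set 1 and 71.97 in set 2.

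The DMAD comparison asked which transcripts depend on DMAD at 6 h. Genes of the late embryo list were lower in the DMAD column, and a smaller number of genes were higher. Among the largest falls were Osi6 (114 to 3.16 FPKM) and Osi7 (60.5 to 1.51), of the Osiris family of cuticle-forming cells, ect (23.1 to 1.13), an ectodermal gene, and TwdlN (10.9 to 0.13), a Tweedle cuticle protein gene. CG9184 (57.7 to 0.52), CG10591 (32.6 to 0.50), CG15212 (21.4 to 0.88) and CG32073 (50.2 to 3.44) completed this group. Among the largest rises were SNCF (2.14 to 16.0 FPKM) and Z600 (0.63 to 5.94), an early zygotic gene that halts mitosis before gastrulation. Mabi (9.94 to 35.7) was higher too, as were dUTPase (1.65 to 6.40), which keeps uracil out of DNA, and net (2.58 to 8.99), a basic helix-loop-helix gene. The others were CG34213 (2.71 to 12.3), CG4186 (1.09 to 6.09) and CG34134 (1.19 to 5.31).

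The late embryo list, made of cuticle, chitin and muscle genes and the synaptic gene nSyb, taken as genes switched on after 6 h, had a median log2 ratio of -1.75, against a central range of -0.28 to 0.22 for random lists. Of its 13 measured members 9 were lower and 0 higher. TwdlM stood at 36.2 FPKM in the control and 5.02 in the DMAD column, the chitin deacetylase genes verm at 32.4 and 5.71 and serp at 16.2 and 2.70, and the muscle actin gene Act57B at 263 and 66.9. The mesoderm and muscle list, which shares wupA and, among measured members, Act57B and Mhc with the former, had a median of -0.57 with 7 of 19 members lower. Among them were Mhc, the muscle myosin heavy chain gene (25.7 to 6.73 FPKM), the troponin T gene up (39.1 to 10.7) and the tropomyosin gene Tm2 (24.6 to 7.39). The hemocyte list (median -0.61, 2 of 10 lower) held the type IV collagen genes Col4a1 (16.5 to 4.56 FPKM) and vkg (7.77 to 2.45), while Ppn stood at 44.5 and 22.2 and Pxn at 6.58 and 3.55.

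Epithelial and gut lists also lay below their random ranges. Dorsal closure and ectoderm adhesion genes had a median of -0.44 with 2 of 12 lower, the septate junction gene Fas3 (28.6 to 6.33 FPKM) and cno (66.3 to 31.5). The apical polarity genes sdt and crb stood at 57.4 and 37.6 FPKM in the control and 34.3 and 24.6 in the DMAD column. Endoderm and gut genes had a median of -0.46, all 10 with a ratio below 0, led by the GATA factor gene GATAe (10.97 to 3.83 FPKM). The Fox gene bin stood at 13.5 and 6.46 FPKM, peb at 46.8 and 25.5 and dve at 8.08 and 4.50. Trachea and epidermis genes had a median of -0.45 with 1 of 10 lower, the apical membrane gene m (2.91 to 0.13 FPKM). The transcription factor genes vvl, trh and grh stood at 32.2, 33.0 and 64.6 in the control and 16.4, 17.2 and 36.9 in the DMAD column. Neural genes (-0.26, 1 of 20 lower) and dorsoventral patterning genes (-0.19, 0 of 19 lower) lay below their ranges as well. Early zygotic genes had a median of -0.09 (1 higher, 2 lower of 31), just under the lower bound of their range at percentile 2.34, and inside it at percentile 2.55 over genes above 0 in both columns.

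Maternal transcripts that are cleared in the embryo had a higher median (0.31, percentile 99.9, 1 of 19 higher). So had the 86 cytoplasmic ribosomal protein genes (0.25, percentile 100), of which 84 had a ratio above 0 and 1 was past the rule of size, lower. After quantile normalization the ribosomal protein genes lay inside their range (0.054, percentile 63.5), and gap and pair-rule genes below theirs (-0.16, percentile 1.19). In the values as deposited, medians inside the random ranges were those of gap and pair-rule (-0.14), Hox (-0.15), germ cell (-0.17), segment polarity (0.01), cell cycle (0.13), Fox family (-0.14), adenine methylation (0.02), heat shock (-0.14) and immune and RNA interference genes (-0.16). The lists of eggshell, adult head and mitochondrial genes, and the list of targets, had fewer than 5 measured members.

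In all, 107 genes were higher and 468 lower of 8669 in the DMAD column, and 11 of 20 lists lay outside their random ranges. After quantile normalization 202 were higher and 360 lower, so the higher share moved from 18.6% to 35.9%. Of the 468 lower genes 82 were listed at 0 in the DMAD column, and among protein-coding genes above 0 in both columns 53 were higher and 361 lower.

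**Figure D1:**
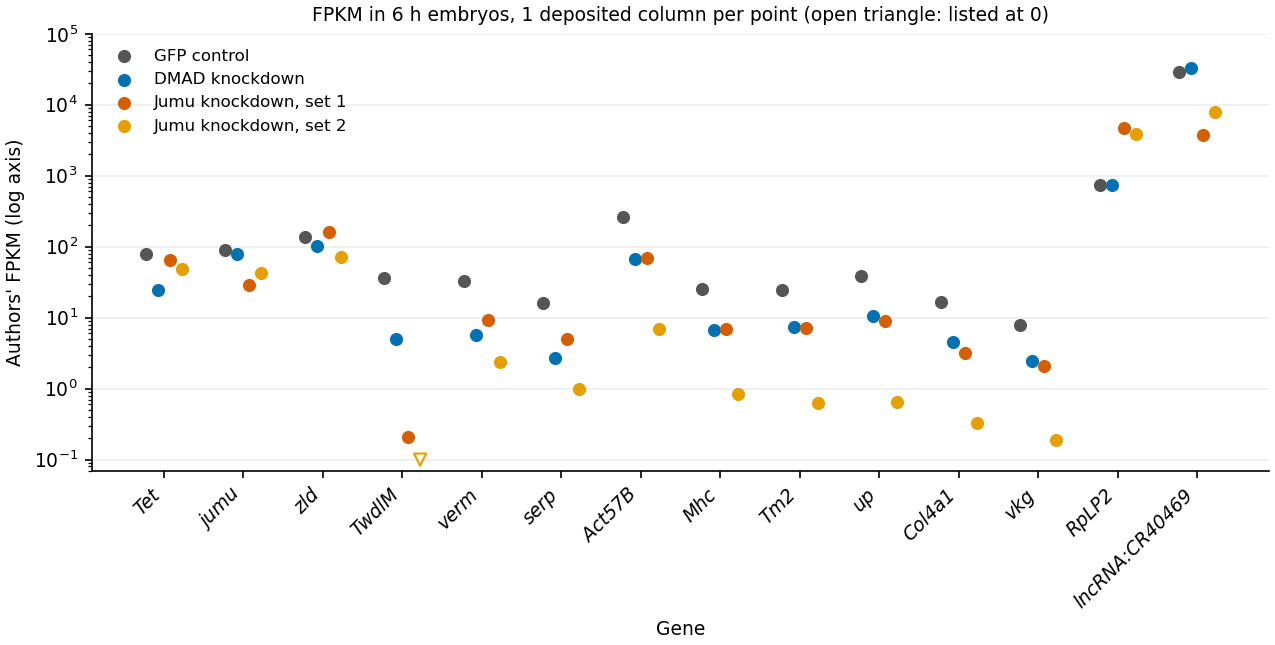
Authors' FPKM on a log axis for 14 genes, with 1 point per deposited column of 6 h embryos (GFP control, DMAD knockdown, and Jumu knockdown sets 1 and 2) and open triangles for genes listed at 0. Tet is lowest in the DMAD column at 24.8 FPKM, jumu is lowest in Jumu set 1 at 29.3, and Act57B lies at 263 in the control and at or below 69.1 in the other columns.

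The Jumu comparison asked which transcripts depend on the proposed 6mA reader. In set 1, genes of the late embryo list were lower. A ribosomal protein gene was among the largest rises of protein-coding genes above 0 in both columns. The cuticle protein genes TwdlM (36.2 to 0.21 FPKM), TwdlD (22.0 to 0.23), Cpr64Ad (18.4 to 1.57) and Cpr51A (16.9 to 1.38) fell, as did CG10591 (32.6 to 1.32), CG2961 (8.23 to 0.20) and CG31777 (24.3 to 2.68). RpLP2, which encodes a protein of the ribosomal stalk, rose from 733 to 4695 FPKM and stood at 3837 in set 2, while the DMAD column held 747. CG13551 (113 to 384 FPKM), the nicotinic acetylcholine receptor gene nAChRalpha4 (5.60 to 22.6), CG44005 (8.78 to 31.8), CG32536 (2.73 to 14.5), CG34134 (1.19 to 6.62) and the antimicrobial peptide gene DptB (1.42 to 6.75) were higher too. The gene lmgB stood at 0.003 FPKM in the control and 10.5 in set 1, too near 0 in the control for a fold to be given.

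The late embryo list had a median of -1.70 in set 1, below its random range of -0.35 to 0.25, and 12 of its 13 measured members were lower. Cpr65Ea stood at 65.0 FPKM in the control and was listed at 0 in set 1, obst-E stood at 3.70 and was listed at 0, and Act57B stood at 263 and 69.1. Hemocyte genes had a median of -0.61 with 3 of 10 lower, namely Col4a1 (16.5 to 3.17 FPKM), vkg (7.77 to 2.07) and Ppn (44.5 to 17.1), with the prophenoloxidase gene PPO2 at 18.4 and 8.96. Mesoderm and muscle genes had 6 of 19 members lower, but their median of -0.17 lay inside the range.

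Heat shock and stress genes lay below their range in set 1 (-0.42, percentile 1.90), with Hsp68 (5.18 to 1.07 FPKM) and Hsp67Bc (3.69 to 0.80) lower, GstD2, a glutathione transferase gene, higher (1.05 to 3.35), and Hsp27 at 79.4 and 40.03. Neural genes (-0.29, 1 of 20 lower) and cell cycle genes (-0.28, 0 of 25 lower) lay below their ranges too. Maternal transcripts lay above theirs (0.33, percentile 99.8, 3 of 19 higher). The cell cycle gene plu (18.4 to 47.7 FPKM), the piRNA pathway gene piwi (4.06 to 10.7) and the anterior determinant bcd (18.6 to 41.7) were higher, and smg, whose product drives maternal mRNA decay, stood at 146 and 277. Germ cell genes lay above their range (0.32, percentile 98.6, 1 of 10 higher), the member past the rule of size being piwi, with pgc at 4.72 and 9.44 FPKM, zpg at 8.05 and 14.7, and tud at 27.9 and 20.3. Immune and RNA interference genes lay above theirs (0.41, 3 of 9 higher, 1 lower). The antimicrobial peptide genes DptA and Mtk were listed at 0 in the control and at 12.8 and 5.19 FPKM in set 1, and PGRP-SB1 was lower (2.31 to 0.52). Over genes above 0 in both columns, the immune list had a median of -0.07 and lay inside its range.

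Early zygotic genes had a median of 0.05 in set 1 (percentile 72.8, 1 higher and 1 lower of 31), and lay inside the random range. So did gap and pair-rule (0.10), segment polarity (0.01), Hox (0.10), dorsoventral (0.03), endoderm (-0.19), trachea and epidermis (-0.22), Fox family (0.01), adenine methylation (-0.06), ribosomal protein (-0.07) and dorsal closure genes (-0.20). In the set 1 column taken over the DMAD column, early zygotic (0.18), gap and pair-rule (0.36), Hox (0.44), endoderm (0.47), immune (0.47) and dorsal closure genes (0.30) lay above their random ranges. Ribosomal protein genes (-0.31) lay below theirs and late embryo genes (0.10) inside.

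In set 1, 195 genes were higher and 476 lower of 8603, and 8 of 20 lists lay outside their random ranges. After quantile normalization 321 were higher and 346 lower, so the higher share moved from 29.1% to 48.1%, and immune genes lay inside their range (percentile 96.6). Of the 476 lower genes 127 were listed at 0 in set 1, the column with the lowest relative depth, and among protein-coding genes above 0 in both columns 134 were higher and 325 lower. Genes with near-identical relatives (Osi, Cpr, Twdl and actin genes, histone and ribosomal RNA copies) and genes that overlap others are uncertain, since the treatment of shared reads and of strand was not stated.

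Set 2 was set against GFP across separately normalised tables, and not against the unused wt column of its own table, which may be its control. In this comparison 397 genes were higher and 643 lower of 8635. Among the largest falls were muscle and cuticle genes, with Osi6 at 0.23 FPKM and Osi7 at 0.04. The muscle LIM protein gene Mlp60A stood at 85.8 FPKM in the control and 1.27 in set 2, Act57B at 6.84, the troponin C gene TpnC47D at 35.2 and 0.17, and up at 0.64. Late embryo genes had a median of -3.85 (12 of 13 lower) and hemocyte genes of -0.63 (4 of 10 lower). These were the 2 lists of the 8 from set 1 that lay outside their range on the same side. Of the other 6, maternal transcripts had a median of -0.03, germ cell genes of 0.02, cell cycle genes of -0.18, neural genes of -0.18, heat shock genes of -0.44 and immune genes of -0.22, all inside their ranges. Early zygotic genes had a median of 0.00 in set 2, inside its range at percentile 63.3. In set 2 over set 1, of the same knockdown but another mRNA kit and table, 256 of 8304 genes were higher and 287 lower. This total of 543 stood beside 575 in the DMAD column and 671 in set 1, both over GFP. Set 1 over the DMAD column gave 639, with 318 of 8364 genes higher and 321 lower. The counts over GFP therefore cannot be read as responses to the knockdowns alone.

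**Figure D2:**
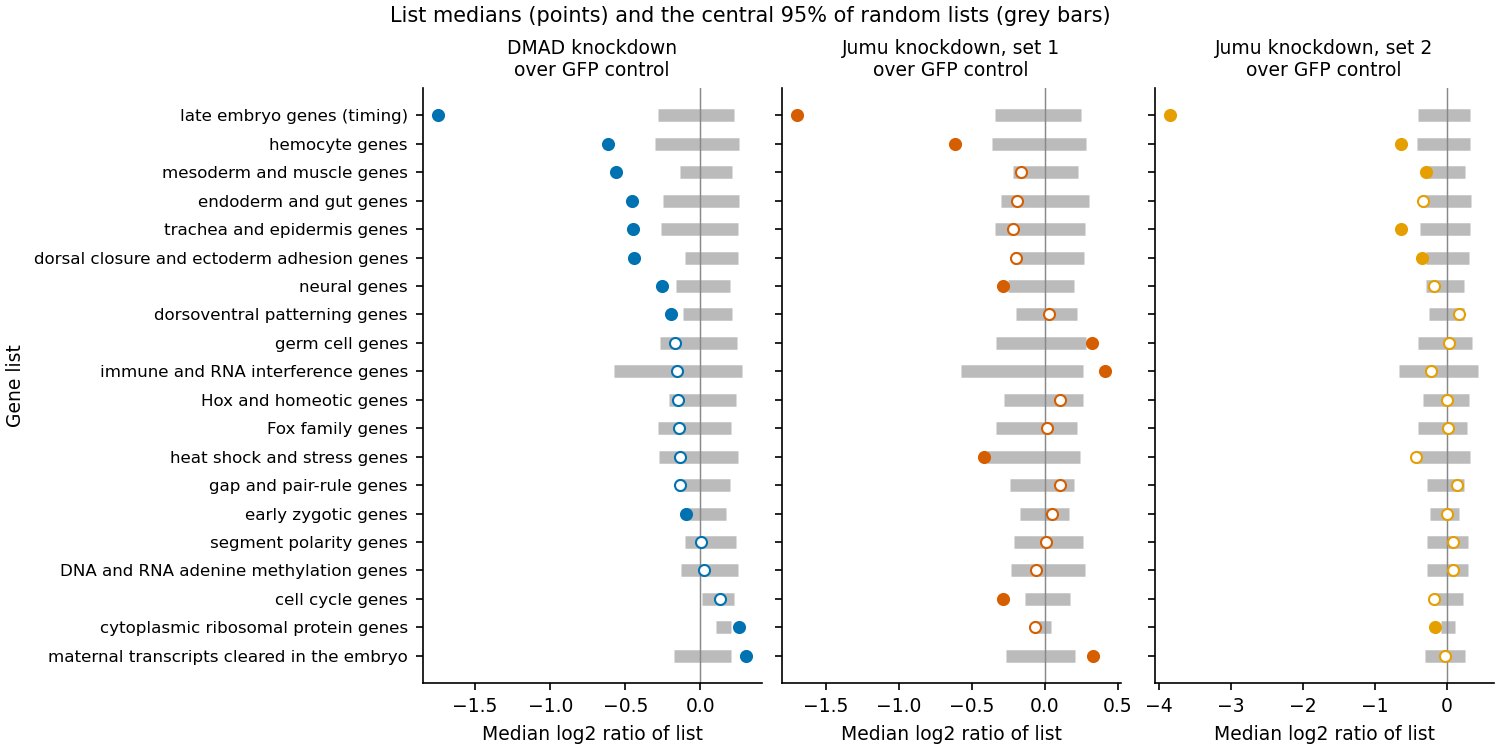
Median log2 ratio of FPKM + 1 over the GFP control for each gene list, in the DMAD knockdown and the 2 Jumu knockdown sets, as filled points outside and open points inside the central 95% of 10000 random lists (grey bars), with a horizontal scale of its own in each panel. Late embryo genes lie at -1.75, -1.70 and -3.85, below the grey bar in each panel, and early zygotic genes at -0.09, 0.05 and 0.00.

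The relation between both knockdowns asked how far DMAD and Jumu affect the same genes. Genes lower in both included TwdlM, Act57B, Mhc, up and Tm2 of the cuticle and muscle, with Mhc at 25.7, 6.73 and 6.99 FPKM and Tm2 at 24.6, 7.39 and 7.22 in the GFP, DMAD and set 1 columns. Osi6 and Osi7 were lower in the DMAD column and less so in set 1, with log2 ratios of -0.76 and -0.48 there. Across 8567 genes the log2 ratios of DMAD and of set 1 had a Pearson r of 0.532 (95% bootstrap interval 0.455 to 0.605) and a Spearman rho of 0.359, where genes are not independent replicates. Both ratios share the GFP column. Columns simulated with equal, independent deviations and a shared control gave a mean r of 0.4995 and a highest r of 0.566, and the observed r lay inside this range. Equal deviations fix the mean r near this value by design. The deviations were drawn from the difference between the DMAD and Jumu columns, which holds any effects of the knockdowns. The simulation therefore cannot show what unchanged columns would give. The simulated covariance was 0.249, beside an observed 0.285, and the ratios had the same direction for 60.2% of genes, against 66.5% in the simulation. Lower in both were 206 genes, against 22.5 for independent lists and 112 in the simulation, and higher in both were 21, against 2.14 and 111. Over the 7810 protein-coding genes above 0 in all columns, r was 0.437 and the covariance 0.109, below the simulated 0.141. Part of any excess may come from the shared GFP column, which could not be split. The ratios of DMAD over GFP and of set 2 over set 1, which share no column, had an r of 0.226 and a rho of 0.231 across 8053 genes.

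The DMAD-CD sites were used to ask whether genes at DNA of 0.75 h embryos pulled down with DMAD-CD are those that change later. In set 1, genes with a site had higher ratios than other genes. Examples, chosen after their values were seen, were nAChRalpha4 (5.60 to 22.6 FPKM, 3 sites), the kinase-like gene Stlk (10.6 to 33.3, 2 sites) and the piRNA pathway gene AGO3 (16.7 to 49.6, 16 sites, 3L 23554593 to 23689640). Others were CG41378 (5.96 to 18.7, 16 sites), Ref1 (181 to 427, 1 site) and CG40006 (3.64 to 9.82, 4 sites). The noncoding lncRNA:CR40469 went the other way, from 29184 to 3689 FPKM. Of these examples, at least CG41378 lay in the 28 bins of 500 kb densest in sites. Genes without a site there had a raised median in set 1 too (0.30). The 300 genes with a site had a median log2 ratio of 0.13 against -0.04 for the other 8303, a difference of 0.17 that lay above the reassignment range of -0.06 to 0.05, with 0 of 100000 reassignments as far out. Past the rule of size, 8.33% of them were higher and 3.00% lower, against 2.05% and 5.62% of other genes. Set 2, which shares the GFP column, gave a mixed result. Its difference of -0.028 lay inside the range of -0.07 to 0.06 when genes were matched on mean FPKM, and above the range of -0.23 to -0.097 when they were matched on gene length. With sites near gene ends alone it was 0.303, above its range of -0.11 to 0.13. In set 2, 11.5% of genes with a site were higher and 7.46% lower, against 4.35% and 7.45% of other genes.

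In the DMAD column, genes with a site had a median of -0.06 against 0.03, a difference of -0.09 with 169 of 100000 reassignments as far out. The difference was -0.152 with sites in the gene body alone (0 of 100000 as far out) and -0.149 over genes outside the 28 bins of 500 kb densest in sites (1 of 100000). With sites near gene ends alone it was 0.052, inside its range of -0.08 to 0.07. Lower genes with sites, chosen after their values were seen, included the nuclear receptor genes Eip75B (5.30 to 0.77 FPKM, 6 sites) and ftz-f1 (17.2 to 5.96, 8 sites). Lower too were heca (16.2 to 4.79, 6 sites), mwh (8.90 to 2.74, 4 sites) and dpy (8.001 to 2.53, 2 sites), and higher were Pka-C3 (2.42 to 6.85, 8 sites) and Sox102F (2.22 to 5.81, 2 sites). Genes with a site were long, with a median of 20538 bp against 2559 bp. Reassignment within deciles of gene length gave a range of -0.26 to -0.14, so the observed -0.09 then lay above it, which turns the direction.

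The comparison of fly head and fat body asked how far 6mA positions are shared between tissues. The fat body was larval, so stage may differ along with tissue, with 1 library each. The highest-scoring head peaks lay at or near the ribosomal RNA genes of the X chromosome, at X 23438735 to 23442109 (score 153850, in no annotated gene) and X 23253129 to 23253788 (62499, in no gene). Below them were X 23205192 to 23206525 (45000, over 28SrRNA-Psi:CR45855 and others) and X 23281773 to 23284175 (39565, in pre-rRNA:CR45856 and 18SrRNA-Psi:CR45861). In fat body the highest-scoring peaks lay at X 23020451 to 23021908 (score 589345, in no gene) and Y 1416983 to 1418203 (273559, in no gene). The next lay on the mitochondrial genome at M 9707 to 13438 (240412), M 1231 to 6303 (162926) and M 6672 to 9272 (141991, over ND4 and ND5, which encode respiratory complex I subunits). Of the knocked-down genes, Tet held 2 head peaks and 7 fat body peaks within the gene or 1 kb of it, the highest at 3L 2840848 to 2841113 (score 103) and 3L 2820111 to 2820501 (score 144). The gene jumu held none in either, and zld held 2 in fat body. Tet is far longer than jumu and zld, and these counts were not set against gene length. Of 5361 head peaks 2496 overlapped a fat body peak, 46.6% (exact binomial interval 45.2 to 47.9), against a mean of 4.09% in shuffles and 5.85% when peaks moved by at most 100 kb.

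Head peaks were concentrated in parts of the genome, since the densest 28 of 280 bins of 500 kb held 39.8% of head peaks, 48.5% of DMAD-CD sites and 21.0% of fat body peaks. The densest bins lay at 2R 2000001 to 2500000 for head (98 peaks), at 3R 1 to 500000 for DMAD-CD (206 sites) and at X 12500001 to 13000000 for fat body (66 peaks). Midpoints lay in genes for 53.9% of head peaks against 67.3% of shuffled ones, and for 44.1% of DMAD-CD sites against 66.6%. They did so for 71.9% of fat body peaks against 69.2%, and the fat body peaks at or above the median score gave 67.4% against 68.9%. Of 13946 protein-coding genes, 1270 held a head peak, 2615 a fat body peak and 578 a DMAD-CD site within the gene or 1 kb of it.

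**Figure D3:**
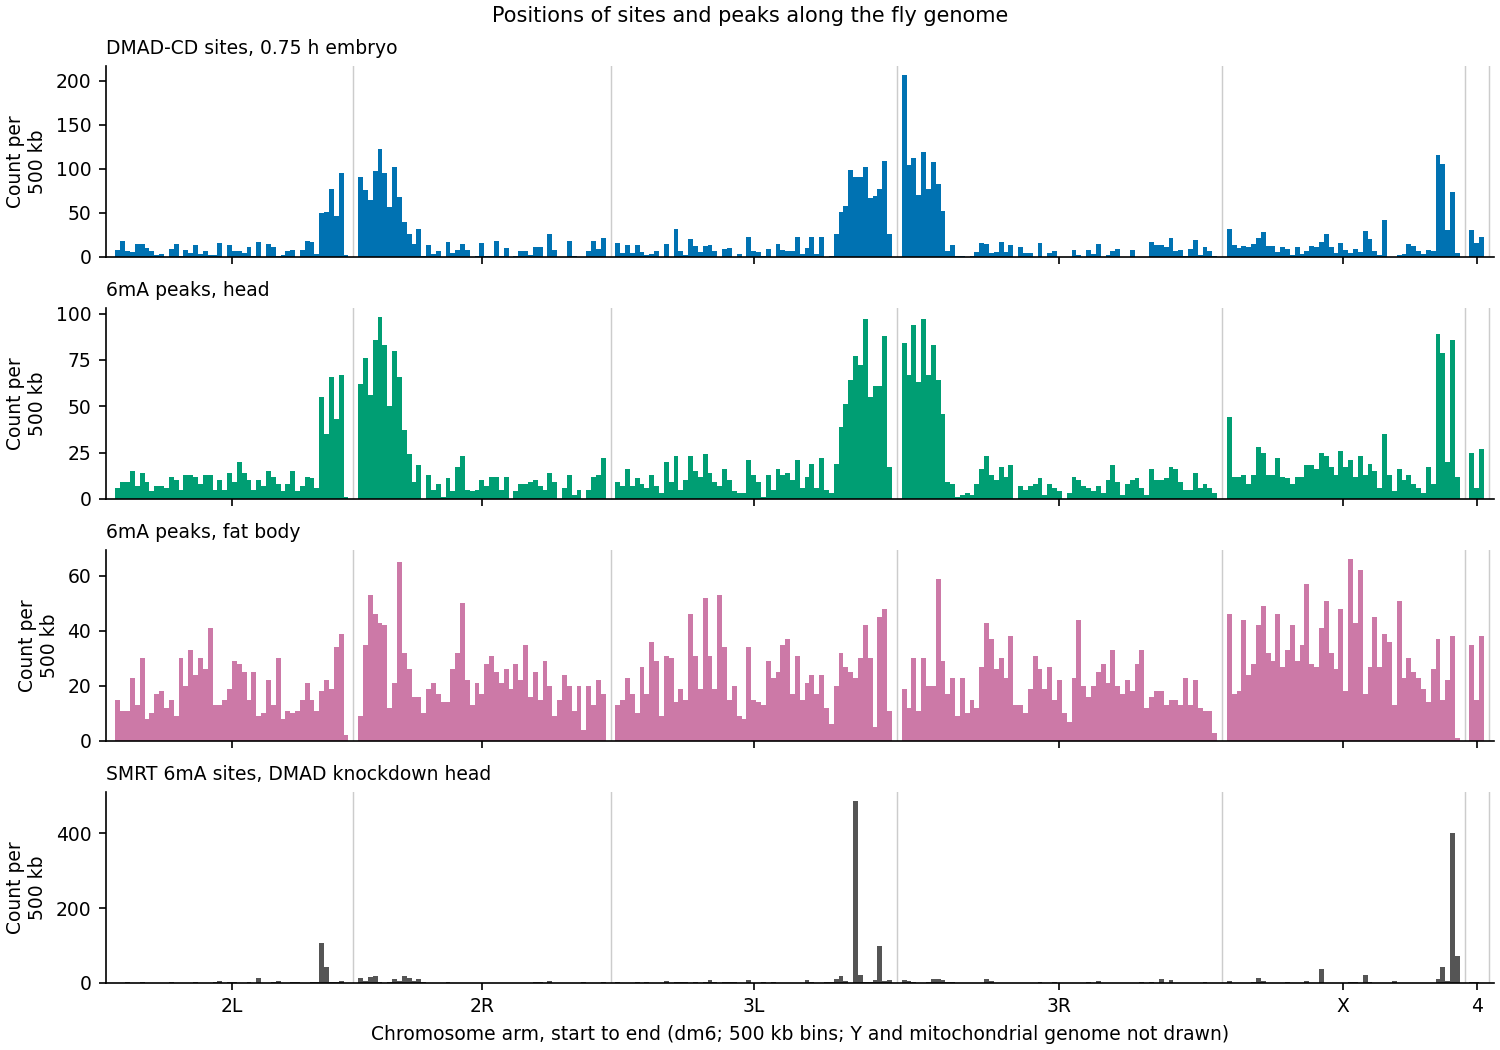
Counts per 500 kb bin along the fly chromosome arms (dm6) of DMAD-CD sites, head 6mA peaks, fat body 6mA peaks and SMRT 6mA sites, with 1 bar per bin. The highest bars hold 206 DMAD-CD sites at the start of 3R, 98 head peaks on 2R and 486 SMRT sites at 3L 24500001 to 25000000, and fat body peaks are spread more evenly.

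Late embryo genes were those most often marked in fat body relative to chance, with a peak at 9 of 19 against 3.46 for genes of the same length. They were Mhc, the myosin light chain genes Mlc1 and Mlc2, the troponin genes wupA and TpnC73F, verm, obst-A, obst-E and the synaptic gene nSyb. This did not pass the correction (adjusted permutation p = 0.0766, Benjamini-Hochberg over 66 tests), and no other list did. Germ cell genes had a head peak at 4 of 11, namely the germ plasm genes osk, vas and tud and the gene ovo, against 1.10 by chance (adjusted permutation p = 0.315). Heat shock genes had one at 3 of 18, DnaJ-1, Hsp23 and Hsp70Ba, against 0.559 (adjusted permutation p = 0.315). Early zygotic genes had a DMAD-CD site at 0 of 35, against 1.33 by chance (adjusted permutation p = 0.855), and a head peak at 4.

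The DMAD-CD sites were compared with antibody peaks to ask whether both mark the same positions. The highest-scoring DMAD-CD sites again lay among ribosomal RNA genes, at X 23239803 to 23240162 in 28SrRNA-Psi:CR40741 (score 42635), X 23214147 to 23215129 in 28SrRNA-Psi:CR45859 (35698) and X 23282721 to 23283353 in pre-rRNA:CR45856 (29232). Others lay in no gene, at X 23430616 to 23432266 (41146) and 3L 27007782 to 27008341 (27403). Tet, jumu and zld held no DMAD-CD site. Of 5570 sites 2773 overlapped a head peak, 49.8% (exact binomial interval 48.5 to 51.1), against 4.05% in shuffles and 11.6% with moves of at most 100 kb. Fat body peaks were overlapped by 1280, 23.0% (interval 21.9 to 24.1), against 4.57% and 6.14%. A total of 1215 head peaks (22.7%) overlapped both a fat body peak and a DMAD-CD site, of which 1199 lay outside repeated gene arrays.

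Single 6mA sites of DMAD knockdown heads were set against head peaks because both describe fly head DNA by unrelated methods. The 1938 SMRT sites (1012 on the plus and 926 on the minus strand) were clustered, with 482 (24.9%) at 3L 24600001 to 24640000 and 530 (27.3%) in repeated gene arrays. Among the latter were 227 in the X ribosomal DNA, 149 in the histone gene cluster at 2L 21404181 to 21543688, 132 on the mitochondrial genome and 22 at the Stellate genes. Head peaks held 548 sites, 28.3% (exact binomial interval 26.3 to 30.3), against 4.59% in shuffles and 9.34% when peaks moved by at most 100 kb. DMAD-CD sites held 698, 36.0% (interval 33.9 to 38.2), against 3.02% and 12.6%, with up to 25.6% in a single shuffle of the latter kind. Fat body peaks held 179, 9.24% (interval 7.98 to 10.6), against 5.62% and 4.77%. The sites held lay in 145 head peaks, 158 DMAD-CD sites and 38 fat body peaks. These intervals treat clustered sites as independent and so are too narrow. Without repeated gene arrays the fat body share was 3.20%, and 11 of 100 shuffles and 1 of 100 moves of at most 100 kb gave as much. Without windows of 10 or more sites it was 5.51%, against at most 4.09% in shuffles and 4.44% in such moves. SMRT sites lay in genes for 23.6% of sites, against 68.6% by chance.

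The mammalian lists asked whether peaks of 6mA recur between tissues. In mouse hippocampus the highest scores lay on the mitochondrial genome, at M 10857 to 16299 (100791) and M 2456 to 5060 (81785), while the highest nuclear peak lay at chromosome 15 87639242 to 87639897 with a score of 509. In mouse spleen the highest were M 11252 to 12064 (681) and, in the nucleus, chromosome 5 76653453 to 76653836 (281). A single rat hippocampus peak spanned M 1 to 16313 with a score of 239541, against 1018 at chromosome 1 56192952 to 56193474, and rat spleen had 7084 at M 12704 to 14381 and 1526 at chromosome 16 21978972 to 21979509. In monkey the interval at chromosome 19 62426565 to 62426751 had the highest score of both tissues, 11699 in brain and 5926 in spleen, and the mitochondrial maximum in brain was 1746. Monkey spleen had 0 mitochondrial peaks. Each input came from another tissue than the enriched one, and the share of mitochondrial DNA in either was not examined. Scores on the mitochondrial genome can therefore not be read as more 6mA there than in the nucleus. Gene annotation of these builds was not used here.

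Overlap between tissues exceeded that of shuffled peaks in each species. Of mouse hippocampus peaks 18.1% (exact binomial interval 17.7 to 18.5) overlapped a spleen peak against 0.506% in shuffles, of rat hippocampus peaks 44.1% (43.5 to 44.7) against 1.49%, and of monkey brain peaks 27.4% (26.6 to 28.2) against 0.474%. Taken from spleen, 25.8% of mouse, 19.6% of rat and 12.1% of monkey peaks overlapped one of the other tissue. Both lists of a species were called against the same input, which came from another tissue, so regions with few input reads can appear in both.

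**Figure D4:**
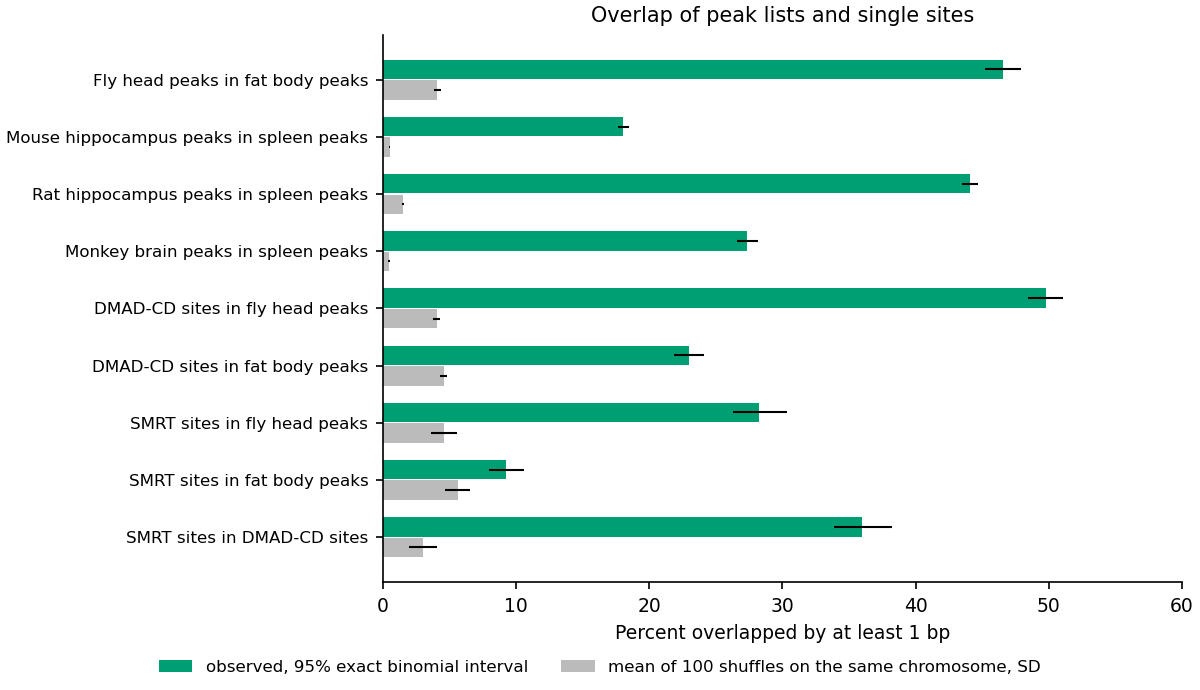
Percent of peaks or single sites overlapped by at least 1 bp, observed with exact 95% binomial intervals, beside the mean and SD of 100 shuffles on the same chromosome. Observed shares run from 9.24% for SMRT sites in fat body peaks to 49.8% for DMAD-CD sites in head peaks, and shuffled means lie at or below 5.62%.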

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

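The comparison between Jumu sets 1 and 2 that picked out the following genes was chosen after the result was seen. Of the genes named in any of the expression comparisons by the rule fixed in advance, or by its later form for protein-coding genes above 0 in both columns, and with a mean FPKM of at least 1 with the control in each set, these stood on opposite sides of the control in sets 1 and 2, at least 1 log2 apart. The difference between the sets was not tested, since each is 1 column and set 2 was normalised in another table.

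CG42518 had a log2 ratio of -2.88 in set 1 and 1.16 in set 2, with 6.37 FPKM in the control, 0.002 in set 1 and 15.5 in set 2. The maternal mRNA decay gene smg had 0.92 in set 1 and -0.21 in set 2, with 146, 277 and 126 FPKM in the control, set 1 and set 2. The pioneer factor gene zld had 0.22 in set 1 and -0.92 in set 2, with 137, 159 and 71.97 FPKM in the same order. SNCF, named in the DMAD comparison, had -0.011 in set 1 and 1.34 in set 2, with 2.14, 2.12 and 6.96 FPKM. The antimicrobial peptide gene DptB, at 1.42, 6.75 and 0.44 FPKM, lay under the minimum of mean FPKM in set 2 and was not compared.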

How the results depend on the processing

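Alternatives with protein-coding genes or genes above 0, with repeated arrays left out, with gene bodies alone, with bins dense in DMAD-CD sites, with moves of at most 100 kb, quantile normalization of the lists, and set 2 for the lists and the DMAD-CD comparison were chosen after seeing the data. For 21 main results and 115 alternatives, 95 kept their direction and their side of the threshold, or stayed within 1.5 times of a count. Of the rest, 10 counts or correlations moved, 3 results were no longer past the threshold and 2 newly were. A further 5 turned direction or crossed to the other side of their range. For 156 single genes, lists and further values with 840 alternatives, 801 kept their side of the threshold. Another 30 were no longer past it and 9 newly were. No single gene turned direction, but set 2 was not among the alternatives for single genes. A list was counted as turned only when it crossed to the opposite side of its random range, and 0 did. List medians could change sign uncounted, as that of immune genes did in Jumu, from 0.41 to -0.22 in set 2. The DMAD count of 575 became 884 with a pseudocount of 0.1, 178 with 5, 244 at a mean FPKM of at least 5 and 280 at a log2 ratio of 1.5, and the Jumu count of 671 became 1011, 213, 320 and 284 under the same settings and 1040 in set 2. The settings other than set 2 change the rule or the genes used, and for set 2 the cause was not tested. After quantile normalization 11 lists in DMAD lay outside their ranges, without ribosomal protein and with gap and pair-rule genes, and 7 in Jumu, without immune genes. The correlation of both knockdowns fell to 0.437 over protein-coding genes above 0. The DMAD-CD difference in Jumu was -0.028 in set 2, inside its range when matched on mean FPKM and above it when matched on gene length, with or without bins, and it was 0.303 and above its range with sites near gene ends alone. In DMAD the difference of -0.095 lay above the reassignment range when matched on gene length, with or without bins, and was 0.052 with sites near gene ends alone. Without repeated arrays 3.20% of SMRT sites lay in fat body peaks, no longer above all shuffles of either kind, and most sites in these peaks had lain in the arrays. Without windows dense in SMRT sites the share was 5.51%, and without the mitochondrial genome alone it was 4.71%, both above all 100 shuffles. Fat body peaks at or above the median score lay in genes for 67.4%, and the cause was not tested. No paired analysis was possible because each condition had 1 FPKM column. For the same reason leaving out replicates, the moderated test and a split control were not run, and neither were score or coverage filters of SMRT sites, their sequence context and promoters by strand. The depth behind FPKM, peaks and SMRT sites is unknown, so no limit from depth can be given.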

Other observations

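The tests of explanations in this part were chosen after the data were seen, except matching on gene length, which had been fixed beforehand as an alternative and was read as a test of this explanation afterwards. Those on bins dense in DMAD-CD sites, and on genes outside them, were added before their own results were seen. Genes in parts of the genome rich in DMAD-CD sites had ratios above those of random lists in the 3 knockdown columns, which share the GFP column and so are not independent of each other. In the 28 densest of 280 bins, genes without a site of their own had a median log2 ratio of 0.21 in the DMAD column, 0.30 in Jumu set 1 and 0.55 in set 2, above the ranges of random lists (percentiles 99.9, 100 and 100), and genes with a site had 0.36, 0.60 and 0.98. Genes there include CG41378 at 5.96, 9.08, 18.7 and 11.7 FPKM in the control, DMAD, set 1 and set 2 columns, CG40472 at 13.5, 18.3, 27.3 and 75.8, and the respiratory complex I subunit gene ND-AGGG at 102, 113, 191 and 398. These genes were chosen after their values were seen.

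Some changes were found in both Jumu columns and not in the DMAD column. RpLP2 stood at 733, 747, 4695 and 3837 FPKM in the control, DMAD, set 1 and set 2 columns, CG13551 at 113, 129, 384 and 417, and the noncoding lncRNA:CR40469 at 29184, 33059, 3689 and 7870. In set 2, some genes of adult tissues were higher, namely the yolk protein genes Yp1 (0.45 to 2.30 FPKM), Yp2 (0.81 to 3.75) and Yp3 (1.39 to 4.64) and the arrestin gene Arr2 (0.58 to 2.91), while the rhodopsin gene ninaE stood at 2.15 and 4.71. Of 5 measured eggshell and yolk genes 3 were higher, and Cp15 and Cp18 had ratios below 0. Of 5 measured adult head and eye genes 1 was higher, and Obp99b and norpA had ratios below 0. These lists are given no median, since Yp1, Yp2 and Arr2 passed the minimum of mean FPKM only through their set 2 values. Trachea and epidermis genes (-0.64), dorsal closure genes (-0.35), mesoderm and muscle genes (-0.29) and ribosomal protein genes (-0.17) lay below their ranges in set 2 and inside them in set 1. In set 2 over set 1, dorsal closure genes (-0.27, percentile 0.960) and ribosomal protein genes (-0.056, percentile 0.280) lay below their ranges, and trachea and epidermis genes (-0.33, percentile 2.81) and mesoderm and muscle genes (-0.13, percentile 11.35) inside.

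Late embryo genes were lower in the DMAD and both Jumu columns. Scaling was examined by quantile normalization, which moved ribosomal protein genes inside their range in the DMAD column. The late embryo median there changed little, from -1.75 to -1.63, and stayed below its own range. Random lists come from the same columns and shift with them, so a median this far out could hardly have come inside. The place outside the range therefore does not weigh against scaling, and lists of set 2 were not normalised in this way. A difference in age or make-up of the collections may account for the pattern in part or in whole. The late embryo list differed as strongly between both Jumu columns, with a median of -2.11 for set 2 over set 1. There 8 of 9 members were lower, although these columns also differ in mRNA kit and table. A younger set 2 would also hold more of the maternal transcripts cleared in the embryo. In set 2 over set 1 these had a median of -0.29, below their range, with 5 of 20 members lower. Age alone thus does not give both medians. Over the control, maternal transcripts lay above their ranges in the DMAD column (0.31) and set 1 (0.33), and inside in set 2 (-0.03). An effect of lower DMAD or Jumu stays open and cannot be told apart from a difference between collections with 1 control column. The median of 0.10 for set 1 over DMAD does not decide between them.

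SMRT sites of DMAD knockdown heads lay inside head peaks more often than in shuffled peaks. Repeated gene arrays and dense clusters were argued against as the whole cause, since 19.4% of the sites outside dense windows still lay in head peaks, against at most 4.09% in 100 shuffles and 9.06% in 100 moves of at most 100 kb. Shared regions at the scale of 100 kb were argued against as well, with a mean of 9.34% for peaks moved by at most 100 kb against the observed 28.3%. Extra copies missing from the assembly could add reads to both methods, and 36 windows of 10 kb held 70.9% of sites, but no coverage was given, so this cannot be told apart from clustered 6mA. No biological explanation was tested.

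Genes with a DMAD-CD site stood apart from other genes in both knockdowns. In the DMAD column gene length may explain why the difference was negative, since reassignment within length deciles gave a mean of -0.20, lower than the observed -0.09. Length alone did not give the observed value, which lay above the range of -0.26 to -0.14, with 104 of 100000 reassignments as far out. In Jumu set 1 gene length (-0.040) and location in site-dense bins (0.016) gave mean differences well under the observed 0.17 and were argued against as the whole cause. Contact of the gene with a site remains a hypothesis, with a difference of 0.16 outside the dense bins in set 1. In set 2 the same difference was -0.057 and inside its range, while matching on gene length put that of all genes above its range. With gene length matched, genes with a site thus lay above the range in the DMAD, set 1 and set 2 columns, whose ratios share the GFP column. Contact can therefore not be told apart from a property of the set 1 column or of the GFP column.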
